A study of Drosophila melanogaster with 20 samples.

How the data were processed

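Total RNA from brains of 20 pools or individuals (the labels do not say which) of W1118 flies was sequenced, 5 libraries for each of 4 groups of sex and diet. Brains were flash frozen, RNA was extracted with Trizol and libraries followed Illumina protocols, per the labels' protocols. Reads were aligned with HISAT2, per the submitters' processing notes, with no version; the counting tool, genome build, annotation and strandedness are not given in the sources used here, so no coordinates are printed. The authors deposited a normalised signal per gene and library, gene counts divided by 1 size factor per library, in 2 tables scaled separately, 1 for each sex. That the values were normalised with DESeq2 and that long non-coding RNAs were removed is per the labels of the deposited tables alone. The name of the female table also mentions males, but its columns are the 10 female libraries, and 0 columns of per-sample values were left unused.

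In each library the values were whole multiples of the value of 1 read: 100% came out whole within a tolerance of 0.01, and whole reads were recovered from them. The tables hold 12206 genes for males and 12015 for females, 11780 of them in both; the lowest sum of a gene over the libraries was 6 reads in each table. Depth was 13901684 to 35077559 recovered reads per library. Of 12441 gene names 12412 matched a gene of the reference gene tables. No mitochondrially encoded gene was in the tables, so that list was not tested. Pairs of libraries of a group were compared by chi-square over genes with 20 or more reads in the pair; the smallest chi-square per degree of freedom was 7.55, so no pair agreed within sampling noise.

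The main test was limma (3.58.1, in R 4.3.3) with an intensity trend on log2(value + 1), 2-sided, on genes with a value of 10 or more in at least 5 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05, LPHC against HPLC within each table. A fold change on this scale understates the change of low genes. The difference between sexes was tested in 1 limma fit over both tables as the male difference minus the female difference, in which a scale factor per table cancels; overlap was tested with Fisher's exact test. Gene lists with 4 or more tested genes were tested with camera at its preset correlation of 0.01 and adjusted over lists, with an estimated correlation as an alternative. Beside it, fry tested whether a list's genes moved on balance one way, which does not compare them with other genes; it called 22 male and 9 female lists, and in either direction 27 and 28. Tests, lists, the rule for named genes and most alternatives were fixed before the data were examined, except the list tests between sexes. That rule takes, per sex, the 10 largest rises and falls past the threshold with a mean of 20 or more in the higher group, up to 4 members with the smallest p of each list, the 10 smallest p for a difference between sexes, and up to 10 genes called in both sexes; of the list members, a part is named in the text.

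The 30 lists fixed were amino acid catabolism, amino acid transporters, antimicrobial peptides and immune response, biogenic amines, carbohydrate digestion and sugar metabolism, circadian clock, insulin and TOR signalling, sleep regulators, neuropeptides, activity-regulated genes, detoxification enzymes, heat shock and stress, lipid synthesis, lipolysis, serine synthesis with tRNA charging and ATF4, cytosolic ribosomal proteins, ribosome biogenesis, nuclear-encoded OXPHOS subunits and mitochondrially encoded genes. The others were markers of neurons, glia, photoreceptors, fat body, gut, haemocytes, muscle, olfactory and taste organs, cuticle and trachea, yolk and eggshell, and the male reproductive tract.

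The fit was checked on simulated reads with 200 genes changed. For the male comparison, with 10101 genes tested, 40%, 82%, 98% and 100% of changes of log2 0.32, 0.58, 1 and 2 were recovered, and 8 of 9901 unchanged genes were called. For the female comparison, with 9839 genes tested, these shares were 44%, 62%, 96% and 98%, and 4 of 9639 unchanged genes were called. Simulated genes varied independently, and far fewer of them changed than were called in the real data, so these shares may not carry over. Alternatives were other pseudocounts, filters and scalings, robust moderation, the replicate number as a block, each library left out, and edgeR (4.0.16, TMM) and DESeq2 (1.42.0) on the recovered whole reads. As that added check, edgeR called 5909 male and 3113 female genes and DESeq2 called 5849 and 3305. Shares of reads were compared with exact permutation tests over 14 comparisons. Where a group held 3 reads or fewer, an exact 95% counting interval is given. Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1 was used for the rest.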

Results

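Brains of *Drosophila melanogaster* (wild-type W1118 flies, 4 to 7 days old) were profiled by RNA sequencing after feeding on diets that differed in protein and carbohydrate. There were 20 libraries in 4 groups of 5: males and females, each on a low-protein, high-carbohydrate diet (LPHC) or a high-protein, low-carbohydrate diet (HPLC). For males, protein to carbohydrate was 0:1 in LPHC and 1:1 in HPLC, both at 180 g/L. For females it was 1:2 at 360 g/L in LPHC and 1:1 at 90 g/L in HPLC. If these concentrations are the sum of protein and carbohydrate, which the labels do not say, male LPHC held 0 g/L protein against 90 g/L in HPLC, while female LPHC held 120 g/L against 45 g/L. The diets of the sexes therefore differed, and sex and diet recipe cannot be separated. The study asks how diet relates to sleep, and the male diets were those with the longest sleep (LPHC) and the shortest (HPLC). Recovered reads per library ranged from 21733987 to 35077559 in male HPLC, 14715340 to 29523858 in male LPHC, 13901684 to 25106655 in female HPLC and 17029184 to 30077141 in female LPHC. No statement says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. All fold changes are LPHC minus HPLC on the log2(value + 1) scale, with limma Benjamini-Hochberg adjusted p, and n = 5 libraries per group throughout.

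The libraries carried RNA known from other tissues, and its share moved with diet. In females, the 3 yolk protein genes took 13.4% ± 1.15 (SD) of reads on HPLC and 7.74% ± 0.770 on LPHC (exact permutation test, two-sided, p = 0.00794, the smallest that 5 against 5 allow; adjusted p = 0.0159 over 14 comparisons of library shares). In males the fat body list took 0.965% ± 0.0755 of reads on HPLC and 0.293% ± 0.0506 on LPHC (exact p = 0.00794, adjusted p = 0.0159). The photoreceptor list rose from 8.51% ± 0.261 to 9.67% ± 0.682 of reads in males (exact p = 0.0159, adjusted p = 0.0278) and from 4.23% ± 0.671 to 5.88% ± 0.555 in females (exact p = 0.00794, adjusted p = 0.0159). Relative to the median gene, the list's median log2 change was −0.01 in males and 0.29 in females, as deposited and with libraries scaled to the same total. The male list therefore did not rise beyond a typical gene. The neuron list rose from 1.06% ± 0.0196 to 1.39% ± 0.131 in males (exact p = 0.00794, adjusted p = 0.0159), and was 0.536% ± 0.0568 and 0.556% ± 0.0646 in females (exact p = 0.595, adjusted p = 0.758). In 1 male library, HPLC replicate 4, yolk protein reads were 0.118%, against 0.00666% to 0.00973% in the other 9 male libraries.

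**Figure D1:**
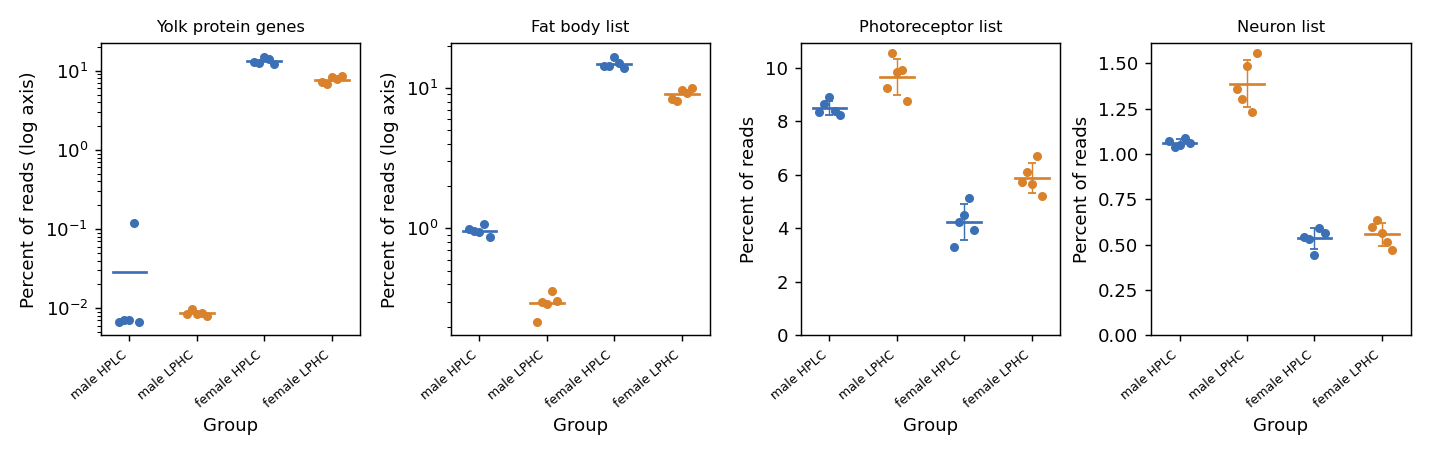
Percent of reads in the 3 yolk protein genes, the fat body list, the photoreceptor list and the neuron list for each library (points; blue HPLC, orange LPHC), with group means (horizontal lines) and, on the linear axes, SD (error bars). The yolk protein and fat body axes are logarithmic, and male HPLC replicate 4 stands at 0.118% in the yolk protein panel.

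The first comparison asked how the male brain transcriptome differed between the long-sleep and short-sleep diets. On LPHC, 24 of 29 amino acid catabolism genes, 31 of 34 immune genes and 75 of 103 detoxification enzymes were lower, and 20 of 23 muscle markers were higher. Lsp2, a larval serum storage protein, went from 14238 ± 1618.5 (SD) on HPLC to 1.08 ± 1.06 on LPHC (log2 −12.91, SE 0.30, adjusted p = 3.09e-13; 6 reads in all LPHC libraries). The glucosidase gene tobi, a target of insulin signalling, fell from 23212.5 ± 3920.2 to 69.9 ± 8.08 (log2 −8.35, SE 0.11, adjusted p = 2.11e-15), a ratio of 332. The genes hll (−8.24), Ugt37B1 (−7.48), the lipase gene mag (−7.22; 5 reads on LPHC), CG3699 (−6.96), CG1979 (−6.96), atk and CG32444 (−5.79) also fell. Lsp1alpha had 2 reads over the LPHC libraries and 1021 over the HPLC libraries, a ratio of 458 with a 95% exact counting interval of 127 to 3789, which covers counting error only. Fewer genes rose strongly on LPHC. The largest rises were in phu (5.83, SE 0.27, from 160 ± 52.7 to 9642 ± 4507), Nepl4 (3.97), CG33093 (3.60), the neuropeptide gene CNMa (3.08), CG15530 (2.76), Root (2.72), CG8665 (2.46), the stress gene TotC (2.41), shd (2.38), which encodes the enzyme that makes 20-hydroxyecdysone, and slam (2.36). TotC varied among LPHC libraries from 715 to 21653, and CG15530 stood at 1.69 with a pseudocount of 8.

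Of 10115 genes tested in males, 5784 (57.2%) passed an adjusted p of 0.05, 2794 higher and 2990 lower on LPHC; 6197 had an unadjusted p under 0.05. Among them 134 were at least 2-fold higher and 950 at least 2-fold lower. The 2 groups did not overlap for 4318 genes (42.7%), against 0.794% by chance. The balance of directions depended on scaling: 48.3% of calls were higher as deposited, 75.1% with libraries scaled to the same total and 68.5% with the same upper quartile. These scalings moved the median gene by 0.25 and 0.16, so that at the same total the medians of ribosomal proteins (−0.31), glia (−0.32), neurons (0.49), neuropeptides (0.74) and sleep regulators (0.45) lay over 1.5 times nearer to or farther from 0 than those given next.

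Genes of amino acid, lipid and sugar metabolism were lower in males on LPHC, where the fat body list took 0.293% of reads against 0.965% on HPLC. Of 29 amino acid catabolism genes tested, 24 were lower and 2 higher (median −2.07; camera adjusted p = 1.08e-11, and adjusted p = 0.153 with an estimated correlation). Among them were Shmt, serine hydroxymethyltransferase (−4.60, SE 0.11), Oat (−3.66), hgo (−2.72) and Hpd (−2.28) of tyrosine breakdown, and Hn, phenylalanine hydroxylase (−2.07). Of 21 lipid synthesis and storage genes, 18 were lower and 0 higher (median −1.44; adjusted p = 3.08e-08, and adjusted p = 0.146 with an estimated correlation). They included AcCoAS (−2.98), ACC (−2.26), the desaturase gene Desat1 (−2.11, from 142644 ± 10396 to 33118.5 ± 3795.6) and ATPCL. Of 24 lipolysis and fatty acid oxidation genes, 20 were lower and 1 higher (median −0.93; adjusted p = 9.12e-08, and adjusted p = 0.274 with an estimated correlation), with the lipase gene bmm at −1.83 and CRAT at −1.73. Of 42 carbohydrate digestion and sugar metabolism genes, 35 were lower and 5 higher (median −0.78; adjusted p = 7.66e-10, and adjusted p = 0.191 with an estimated correlation). Sodh-1 (−4.88), Men, malic enzyme (−3.11), and fbp, fructose bisphosphatase (−2.74), were among those that fell. Serine synthesis, tRNA charging and ATF4 genes as a list did not pass (6 higher and 13 lower of 29, median −0.11, which turns to 0.14 at the same total and 0.05 at the same upper quartile; adjusted p = 0.186), though it did without male LPHC replicate 4 (0.0464; adjusted p = 0.867 with an estimated correlation), and its serine synthesis members CG11899 (−3.08), CG6287 (−2.24) and aay (−2.09) fell.

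Markers of fat body, glia and immunity were also lower in males on LPHC. Of 17 fat body markers 13 were lower and 0 higher (median −1.92; adjusted p = 1.46e-06, and adjusted p = 0.146 with an estimated correlation), among them CG16758 (−3.60) and Lsp1beta (−3.48). The fat body transcript apolpp, picked out after its values were seen, fell by 2.08. Of 34 antimicrobial peptide and immune genes 31 were lower and 0 higher (median −1.31; adjusted p = 7.87e-09, and adjusted p = 0.146 with an estimated correlation), with the recognition protein gene PGRP-SD at −3.02 and the NF-kappaB gene Rel at −1.06. Of 103 detoxification enzymes 75 were lower and 6 higher (median −0.85; adjusted p = 1.65e-12, and adjusted p = 0.146 with an estimated correlation), including Cyp6g1 (−3.69) and Cyp4s3 (−3.13). Of 85 cytosolic ribosomal protein genes 80 were lower and 0 higher (median −0.57; adjusted p = 3.15e-15, and adjusted p = 0.454 with an estimated correlation), with RpS13 at −1.06 and RpLP0 at −0.87. Of 20 glia markers 16 were lower and 0 higher (median −0.57; adjusted p = 0.000543, and adjusted p = 0.274 with an estimated correlation), with the glutamate transporter gene Eaat1 at −1.24 and Idgf6 at −1.73. Of 9 gut digestive enzymes 6 were lower (median −1.70; adjusted p = 0.0123, and adjusted p = 0.146 with an estimated correlation), a call lost when any single male HPLC library was left out (adjusted p 0.0835 to 0.113) and without a filter (0.0926).

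Muscle, neuropeptide and neuronal genes were higher in males on LPHC. Of 23 muscle markers 20 were higher and 1 lower (median 0.72; adjusted p = 2.72e-08, and adjusted p = 0.274 with an estimated correlation), with TpnC41C at 1.56 and Act87E at 1.36. Of 34 neuropeptide and peptide hormone genes 21 were higher and 5 lower (median 0.49; adjusted p = 0.000243, and adjusted p = 0.454 with an estimated correlation). The insulin-like peptide gene Ilp3 rose from 135 ± 26.3 to 539 ± 120 (1.99) and Proc by 0.90, while CCHa2, a peptide hormone, fell (−2.93). Of 39 sleep regulators 19 were higher and 6 lower (median 0.20; adjusted p = 0.0317, and adjusted p = 0.638 with an estimated correlation), a call lost without male LPHC replicate 5 (adjusted p = 0.0616). Dop1R2, a dopamine receptor gene (0.57), and the neuropeptide gene sNPF (0.50; 0.75 at the same total) rose, and Egfr (−0.92) and fabp (−0.62; −0.37 at the same total) fell. The neuron and synapse markers moved in the same direction, with 12 of 19 higher and 1 lower (median 0.24; adjusted p = 0.0101, and adjusted p = 0.638 with an estimated correlation), including elav (0.33; 0.58 at the same total) and Gad1 (0.29; 0.54). None of the 14 male list calls held with an estimated correlation between genes. Counts of members past the threshold were nearly the same when adjusted over the list alone, at most 1 gene apart except in ribosome biogenesis (1 higher and 3 lower, against 3 and 4 over all genes).

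**Figure D2:**
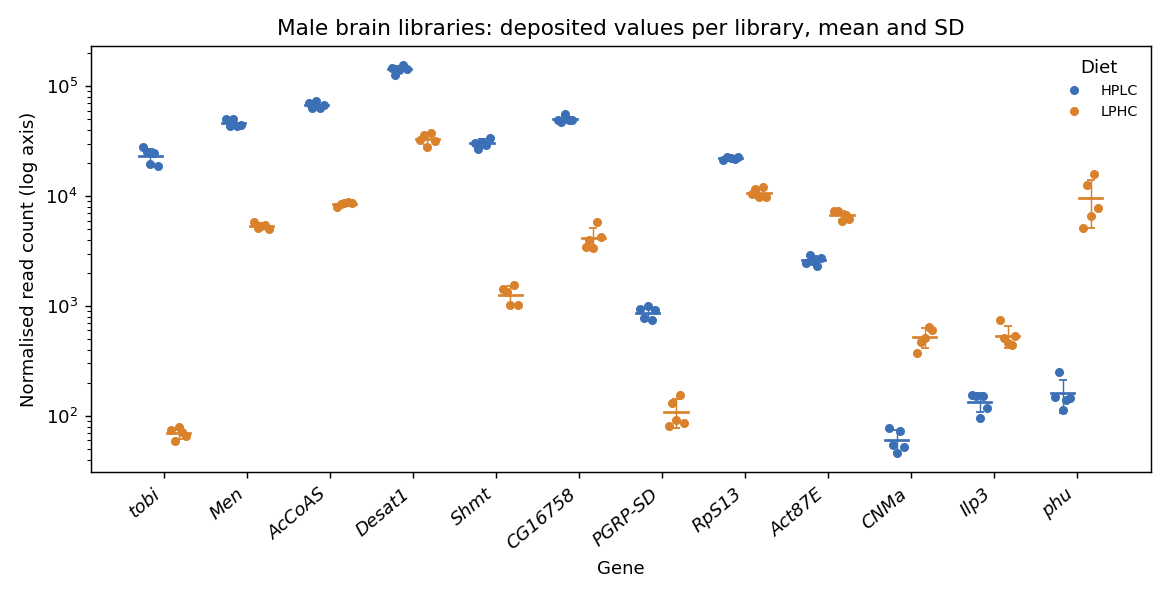
Deposited normalised read counts (log axis) of 12 genes in each male library (points; blue HPLC, orange LPHC), with group means (lines) and SD (error bars), n = 5 per group. The groups do not overlap for any of these genes, and tobi lies between 58.6 and 79.3 on LPHC against 18915.6 or more on HPLC.

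The second comparison contrasted the 2 female diets, which differed in concentration as well as in ratio. On LPHC, 26 of 30 ribosome biogenesis genes and 14 of 22 heat shock and stress genes were higher, and 19 of 30 amino acid catabolism genes were lower. The glutathione transferase gene GstD6 went from 6.16 ± 1.78 (SD) on HPLC to 243 ± 39.0 on LPHC (log2 5.11, SE 0.20, adjusted p = 2.3e-10), GstD7 rose by 5.41, and GstE1 rose from 4476 ± 243 to 19952.6 ± 1584 (2.15, SE 0.07, adjusted p = 7.9e-11). The cytochrome P450 gene Cyp4e3 rose from 922 ± 322 to 22254 ± 4316 (4.65). The other large rises were in Obp99d (5.58), CG5246 (5.48), CG33003 (5.41), Tim17a1 (5.22), CG33299 (4.79), CG4269 (4.75) and CG31296 (4.71), with HPLC means from 0.820 to 12.8. With a pseudocount of 8 in place of 1, CG5246 stood at 3.38, CG33003 at 3.39, GstD7 at 3.28 and Tim17a1 at 2.98. Dup99B had 1 read over the HPLC libraries and 246 over the LPHC libraries, a ratio of 177 with a 95% exact counting interval of 31.5 to 7023. Dup99B, GstD6, GstD7, CG33003, Tim17a1, CG33299, CG4269 and CG31296 have a gene on the same strand within 5000 bases upstream. Read-through from that gene, weighed below, stays open for these rises except that of CG4269. The gene upstream of CG4269 had a mean of 12.0 on LPHC, against 372 for CG4269, which argues against read-through there. The largest falls were in CG10073 (−2.63), CG33093 (−2.55; −1.49 with a pseudocount of 8), the secreted immune factor gene Diedel (−2.54), CG3999 (−2.47), CG31683 (−2.38), Cyp4s3 (−2.36), CG9616 (−2.36), meep (−2.33), the stress gene TotX (−2.29) and CG7763 (−2.28). The yolk protein genes Yp3 (−1.23) and Yp2 fell, Yp2 from 1159720 ± 139538 to 580823 ± 73590.

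Of 9932 genes tested in females, 3133 (31.5%) passed, 1662 higher and 1471 lower on LPHC; 4094 had an unadjusted p under 0.05. Among them 382 were at least 2-fold higher and 160 at least 2-fold lower. The groups did not overlap for 2197 genes (22.1%), against 0.794% by chance. Of the calls 53.0% were higher as deposited and 81.4% with libraries scaled to the same total, which moved the median gene by 0.16. At the same total the medians of photoreceptors (0.44), activity-regulated genes (0.42), the serine and tRNA list (0.37), amino acid catabolism (−0.30), immune genes (−0.31) and insulin and TOR genes (−0.01) lay over 1.5 times from those given next.

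Ribosome biogenesis and heat shock genes were higher in females on LPHC. Of 30 ribosome biogenesis genes 26 were higher and 0 lower (median 0.50; camera adjusted p = 5.44e-11, and adjusted p = 0.495 with an estimated correlation), including nclb (1.14), nop5 (1.04) and Fib, fibrillarin (0.99). Of 84 cytosolic ribosomal protein genes 13 were lower and 1 higher (median −0.14, turning to 0.02 at the same total; adjusted p = 0.000236, and adjusted p = 0.813 with an estimated correlation), among them RpS20 (−0.50) and RpS2 (−0.44; −0.28 at the same total). The share of reads in this list was 9.12% ± 0.534 on HPLC and 9.31% ± 0.693 on LPHC (exact permutation test p = 0.651, adjusted p = 0.759). Of 22 heat shock and stress genes 14 were higher and 4 lower (median 1.32; adjusted p = 8.51e-05, and adjusted p = 0.495 with an estimated correlation). Hsp70Ab (3.49), Hsp70Aa (3.36), Hsp68 (2.81) and the co-chaperone gene DnaJ-1 (1.44) rose, and the 4 that fell were Turandot genes, TotX and, picked out after their values were seen, TotA (−1.63), TotC (−1.68) and TotM (−1.58). Reads of the near-identical Hsp70 copies can be split between them, so their separate values are uncertain. Of 29 serine synthesis, tRNA charging and ATF4 genes 13 were higher and 4 lower (median 0.21; adjusted p = 0.00283, and adjusted p = 0.813 with an estimated correlation; 18 higher when adjusted over the list alone), with asparagine synthetase AsnS at 2.21 and AspRS at 0.89, while the serine synthesis gene CG6287 fell (−1.02). Of 104 detoxification enzymes 26 were higher and 33 lower (median 0.05, and 0.22 at the same total; adjusted p = 0.968), GstD2 rising by 2.36. Adjusted over the list alone, ribosome biogenesis had 27 higher and 1 lower, ribosomal proteins 1 and 10, heat shock 15 and 4, and detoxification 30 and 36.

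In females, 19 of 30 amino acid catabolism genes and 18 of 38 immune genes were lower on LPHC, where yolk protein genes took 7.74% of reads against 13.4% on HPLC. Of the catabolism genes 1 was higher (median −0.46; adjusted p = 8.44e-08, and adjusted p = 0.495 with an estimated correlation), including Sardh (−2.07), CG8745 (−1.42) and hgo (−1.24). Of the immune genes 6 were higher and 14 did not pass (median −0.47, mean −0.10; adjusted p = 0.0205, and adjusted p = 0.813 with an estimated correlation). BomBc2 (−1.01) and BomS6 (−0.96) fell and Listericin, an antimicrobial protein gene, rose (1.96). The immune call was lost without female HPLC replicate 4 (adjusted p = 0.0788) or female LPHC replicate 4 (0.0503). Adjusted over the list alone, catabolism had 1 higher and 20 lower and immune genes 7 and 19. Of 24 insulin and TOR genes 10 were lower and 2 higher (median −0.17; adjusted p = 0.0272, and adjusted p = 0.813 with an estimated correlation). Lst (−1.05), a peptide that limits insulin release, and Ilp6 (−0.84) fell, and the insulin antagonist ImpL2 (1.18) and the leptin-like upd2 (2.94) rose. That call was lost without female HPLC replicate 1 (adjusted p = 0.0513) or female LPHC replicate 4 (0.0503).

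In females, sleep regulators passed with few individual calls, 4 lower and 1 higher of 39 (median −0.14, turning to 0.02 at the same total; adjusted p = 0.0272, and adjusted p = 0.813 with an estimated correlation). SIFa (−0.96), Pka-C1 (−0.66) and Gat (−0.59) fell and rho rose (0.59). The call was lost at the same total (adjusted p = 0.0637), and without female HPLC replicate 4 (0.0518), female LPHC replicate 4 (0.0654) or female LPHC replicate 5 (0.0503). Of 23 photoreceptor markers 8 were higher and 0 lower (median 0.27; adjusted p = 0.0205, and adjusted p = 0.813 with an estimated correlation), with Rh2, the opsin of the ocelli, at 1.32 and trp at 0.40. Of 18 activity-regulated genes 8 were higher and 0 lower (median 0.25; adjusted p = 0.0453, and adjusted p = 0.813 with an estimated correlation), with Arc2 at 1.37 and Jra at 0.39, and 9 higher when adjusted over the list alone. This call was lost at the same total (0.0659) and without female HPLC replicate 2 (0.058) or 3 (0.108) or female LPHC replicate 1 (0.0686) or 2 (0.0726). Nuclear-encoded OXPHOS subunits passed with 5 lower and 2 higher of 63 (median −0.12, turning to 0.04 at the same total; adjusted p = 0.0337, and adjusted p = 0.895 with an estimated correlation), and 0 lower when adjusted over the list alone. That call was lost in both rescalings (0.161 and 0.053), with no filter (0.0641), without female HPLC replicate 3 (0.304) or 4 (0.102), and without female LPHC replicate 1 (0.111), 2 (0.176) or 3 (0.0896). None of the 11 female list calls held with an estimated correlation.

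**Figure D3:**
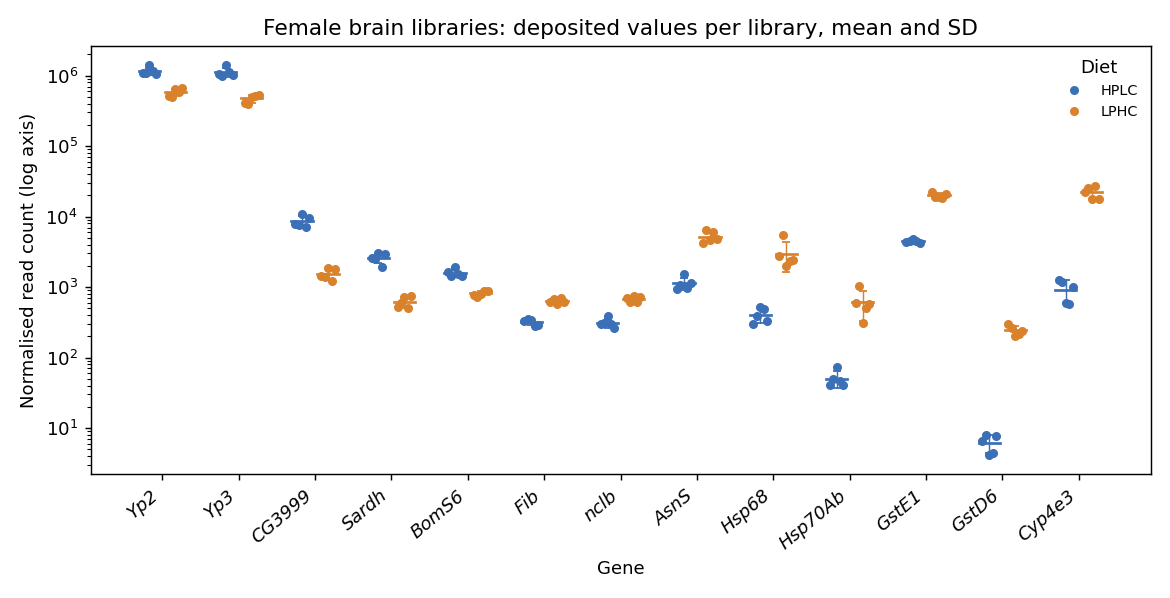
Deposited normalised read counts (log axis) of 13 genes in each female library (points; blue HPLC, orange LPHC), with group means (lines) and SD (error bars), n = 5 per group. Every LPHC library lies below every HPLC library for Yp2, Yp3, CG3999, Sardh and BomS6 and above it for the other 8 genes.

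**Figure D4:**
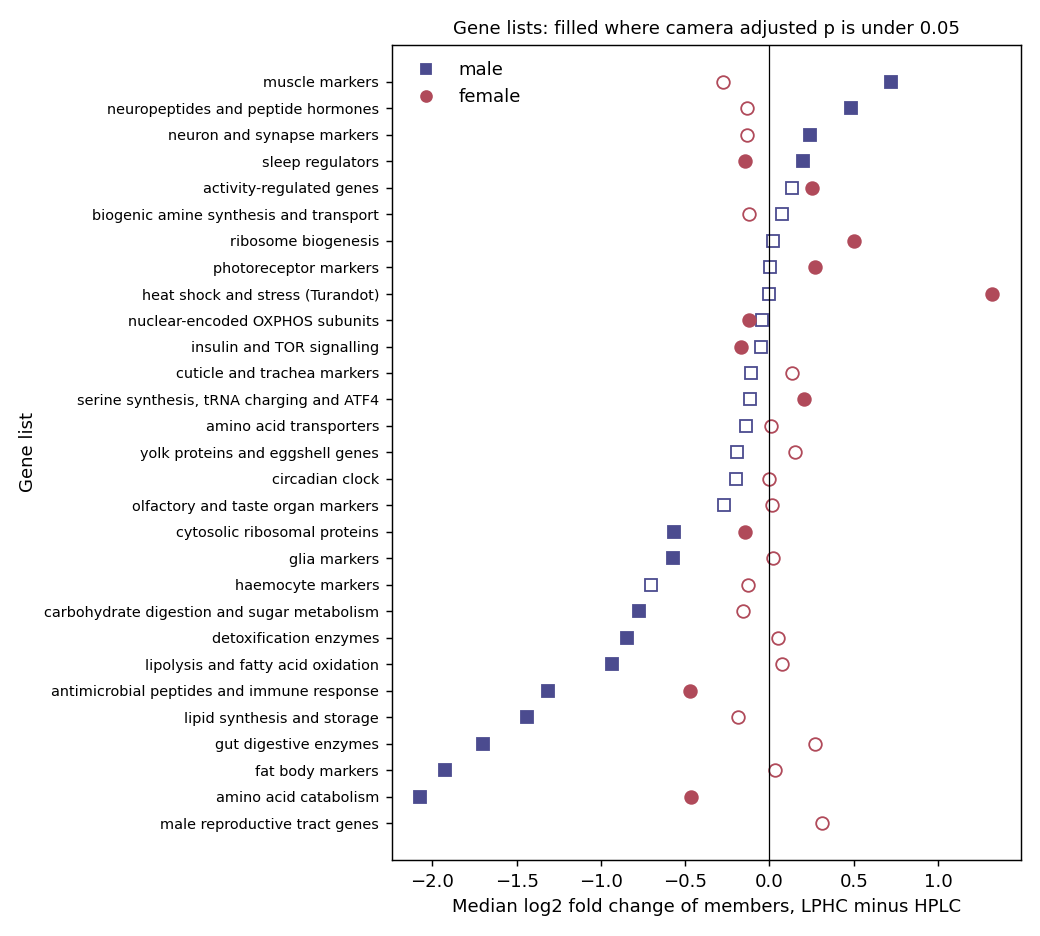
Median log2 fold change (LPHC minus HPLC, deposited scaling) of the tested members of each gene list in males (squares) and females (circles). Filled symbols mark lists with a camera adjusted p under 0.05 at a preset correlation of 0.01, 14 of 28 in males and 11 of 29 in females, of which 0 and 0 hold with an estimated correlation (smallest adjusted p = 0.146 and 0.495); at the same total, among filled symbols, the female medians of ribosomal proteins, OXPHOS subunits and sleep regulators turn positive.

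The third comparison asked whether diet differences were shared by the sexes. Several of the largest male falls had values near 0 in females. Lsp2 was −12.91 in males and −0.18 (adjusted p = 0.261) in females, a difference of −12.73 (SE 0.34, adjusted p = 4.57e-18), and tobi was −8.35 and −0.17 (adjusted p = 0.549; difference −8.18, adjusted p = 5.62e-17; the female value was −0.39, adjusted p = 0.0241, without female HPLC replicate 4). CG32444 and CG10361 fell by 5.79 and 4.20 in males and stood at 0.06 and −0.00 in females. Other genes moved in opposite directions. CG16898 fell by 4.91 in males and rose by 4.13 in females, CG9733 fell by 2.06 and rose by 3.43, CG1979 fell by 6.96 and rose by 1.19, CG7675 fell by 1.62 and rose by 1.65, CG10621 fell by 5.39 and rose by 0.68, and Men fell by 3.11 and rose by 0.25. The female rise of Men was 0.41 at the same total and was lost with no filter (adjusted p = 0.0566) and without female HPLC replicate 2 (0.0556) or female LPHC replicate 3 (0.0577). CG9701 (−2.74 and 3.76), Muc68Ca (−3.81 and 2.52) and CG9519 (−2.14 and 2.35) were also opposite in males and females. Genes that moved in the same direction included Nepl4, higher in both (3.97 and 2.94), and Cyp4s3 (−3.13 and −2.36), CG3999 (−5.27 and −2.47), CG10962 (−3.67 and −2.13) and CG5955 (−3.11 and −1.18), lower in both. The size of the change still differed between the sexes for each of them, from CG3999 (difference −2.80, adjusted p = 2.81e-09) to Cyp4s3 (−0.77, adjusted p = 0.000544).

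Of 9766 genes tested in both sexes, 5106 (52.3%) had a diet difference that differed between males and females, 2217 with a higher and 2889 with a lower male difference; 5623 had an unadjusted p under 0.05. Genes lower in both sexes numbered 706, against 446 for independent lists (Fisher exact test, odds ratio 2.47, p = 6.06e-54), and genes higher in both numbered 244, against 440 (odds ratio 0.421, p = 2.19e-36). Genes lower in males and higher in females numbered 657, against 484 (Fisher exact test, odds ratio 1.78, p = 6.42e-24), and the reverse 399, against 406 (odds ratio 0.972, p = 0.681). In all, 950 genes were shared in direction and 1056 were opposite. Scaling decided these splits: at the same total 1965 genes shared a direction, 1552 of them higher, and 810 were opposite, 649 of them lower in males and higher in females and 161 the reverse. There 52.8% of the 5286 genes that differed had a higher male difference, as did 58.9% of 5496 at the same upper quartile, against 43.4% as deposited. Across the 9766 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.03 and Spearman's rho −0.05.

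**Figure D5:**
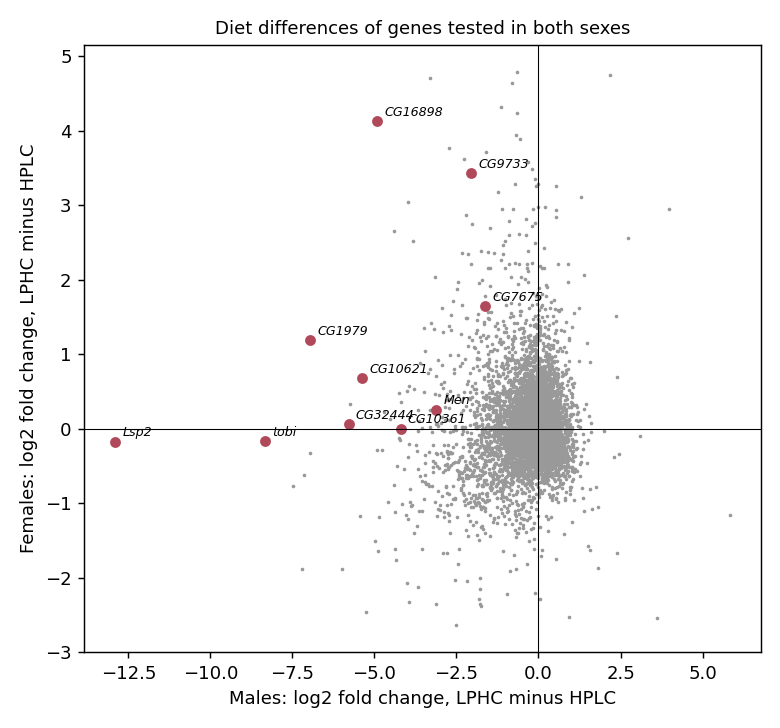
Log2 fold change (LPHC minus HPLC) in males (x axis) against females (y axis) for each of 9766 genes tested in both (grey points). The 10 genes with the smallest p for a difference between the sexes are named in red; CG16898 lies at −4.91 in males and 4.13 in females.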

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

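The weighing of the fat body, yolk protein and low-level gene patterns rests on tests chosen after the results were seen, except the test for genomic DNA. The limit for the test of a wrong label was also changed after values were seen, because no library was able to meet the first one, and so was that for RNA of male reproductive tissue, because a median over members that go both ways decides nothing.

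The diet difference differed between the sexes for 5106 genes, and for 113 of the 125 named genes tested. Named genes were chosen for large changes or small p, 10 of them by this same test, so that share is partly built in. As male minus female log2 differences (LPHC minus HPLC in each), metabolic genes were Shmt −3.61, Oat −3.11, hgo −1.48, Hpd −1.31, Hn −1.71, Sardh −1.94, CG3999 −2.80, CG8745 2.18, CG11899 −3.15, CG6287 −1.22, aay −2.34, AsnS −3.10, AspRS −1.32, AcCoAS −2.65, ATPCL −1.41, ACC −1.38, Desat1 −1.56, FASN2 −4.21, Elovl7 −2.51, bmm −1.52, CRAT −1.34, Sodh-1 −3.68, Men −3.36, fbp −2.86, sug −0.92 and Amy-p −2.86. Storage, detoxification and immune genes were Lsp2 −12.73, Lsp1alpha −6.51, Lsp1beta −3.98, tobi −8.18, CG16758 −2.96, mag −5.33, Ugt37B1 −6.70, Cyp6g1 −2.39, Cyp4s3 −0.77, Cyp4e3 −5.46, GstD2 −3.72, GstE1 −3.65, PGRP-SD −2.49, Rel −1.41, Listericin −3.76, BomS6 −0.72, srp −2.51 and Diedel 3.45. Stress, ribosomal and ribosome biogenesis genes were Hsp70Ab −3.67, Hsp70Aa −3.47, Hsp68 −3.20, DnaJ-1 −0.92, TotC 4.08, TotX 2.35, RpS13 −0.92, RpLP0 −0.72, RpS20 −0.45, Fib −0.69, nclb −1.41 and nop5 −1.11. Brain, signalling, eye, glial and muscle genes were elav 0.40, Gad1 0.46, sNPF 0.63, Dop1R2 0.83, Egfr −0.72, fabp −0.50, Pka-C1 0.44, SIFa 1.38, rho −0.66, CNMa 3.18, CCHa2 −3.47, Proc 1.32, Ilp3 2.02, Ilp5 −1.11, ImpL2 −1.22, upd2 −2.41, foxo −0.26, Lst −0.69, ple −1.33, cry −0.86, cwo −0.71, vri −0.69, Arc1 1.16, Arc2 −1.36, Jra −0.35, Eaat1 −1.58, Idgf6 −1.72, Rh2 −4.0, Rh5 −2.45, Act87E 1.44 and TpnC41C 2.37. The other named genes were CG16898 −9.04, CG1979 −8.15, hll −8.10, CG31296 −8.00, CG3699 −6.64, CG9701 −6.50, Muc68Ca −6.34, CG10621 −6.06, CG32444 −5.85, CG9733 −5.49, CG33299 −5.44, CG9519 −4.49, CG10361 −4.20, atk −4.12, CG7675 −3.27, CG4269 −2.56, CG5955 −1.93, meep −1.62, CG10962 −1.54, CG9616 0.57, slam 0.84, Nepl4 1.03, shd 1.70, CG8665 2.80, CG33093 6.15 and phu 7.00.

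For 16 lists the difference between sexes passed at the preset correlation, and for none of these with an estimated correlation (adjusted p from 0.0817 to 0.583 with an estimated correlation). Median male minus female differences were −2.57 for gut enzymes, −1.71 for fat body markers, −1.42 for amino acid catabolism, −1.16 for lipid synthesis, −1.14 for lipolysis, −0.98 for immune genes, −0.78 for detoxification, −0.65 for the sugar list, −0.51 for ribosome biogenesis, −0.45 for ribosomal proteins, −0.37 for serine synthesis with tRNA charging and ATF4, −0.33 for glia, 0.35 for sleep regulators, 0.36 for neurons, 0.59 for neuropeptides and 0.90 for muscle. The heat shock and stress list (−1.41) did not pass (adjusted p = 0.0515, and adjusted p = 0.570 with an estimated correlation), but did at the same total (0.0265), at the same upper quartile (0.0109) and without male HPLC replicate 1 (0.0370), 3 (0.0474) or 4 (0.0239), male LPHC replicate 1 (0.0261), female HPLC replicate 1 (0.0366), 2 (0.0472) or 5 (0.0460) or female LPHC replicate 3 (0.0405). OXPHOS subunits (0.07; adjusted p = 0.171, and adjusted p = 0.790 with an estimated correlation) passed without female HPLC replicate 5 (0.0354) or female LPHC replicate 4 (0.0333), and olfactory and taste markers (−0.71; adjusted p = 0.123, and adjusted p = 0.519 with an estimated correlation) with a filter of 50 (0.0292).

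One library lay far from the other 4 of its group in 19 of 340 sets of values, where chance sets apart about 1 in 20, or 17. Values stood high in male HPLC for ACC in replicate 1 (49373, others at most 43286), phu in replicate 2 (251, 148), CG16758 in replicate 3 (55625, 49389) and sNPF in replicate 4 (6009, 5680), and in male LPHC replicate 4 for Egfr (2593, 2184) and TotC (21653, 6650). In female HPLC, replicate 3 was high for AspRS (449, 334), CG10361 (1696, 1387), CG7763 (1057, 708), Hsp70Ab (73.4, 49.5) and meep (152, 117), replicate 1 for ple (2227, 2025) and replicate 5 for Dup99B (1.30, 0). In female LPHC, replicate 4 was high for CG10621 (28953, 24064) and low for CG1979 (719, others at least 934), CG9701 (1207, 2206) and ple (2856, 3920), and replicate 2 was high for Hsp68 (5398, 2795). The yolk protein share of male HPLC replicate 4 was 0.118%, against 0.00666% to 0.00709% in the other 4.

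Fat body markers fell in males on LPHC, and less fat tissue in those libraries may explain part of it. Of the 13 markers that fell, 6 fell further than apolpp (−2.08) by more than 2 combined standard errors, from −3.15 to −12.91. An equal loss of tissue forbids this for those 6 only if apolpp is made in that tissue alone, which was not tested. The other 7 ranged over 1.64 log2 units, from −2.08 to −0.44, and for them less tissue and lower expression cannot be told apart, since both change with diet. A lower fat share would lift all other tissues alike. The medians of muscle and photoreceptor markers differed by 0.72 (permutation test over genes, which takes them as independent, p = 4e-05), and glia stood at −0.57. These values argue against it as the whole of the muscle rise. Neuron markers (median 0.24, 12 of 19 higher and 1 lower) were not compared in this way. An equal lift would not lower glia, where 16 of 20 markers were lower and 0 higher. This argues against a lower fat share as the whole of the neuron rise, while for a part of that rise a lower fat share stays open. Less fat tissue also stays open for the metabolic lists that fell, although members such as Shmt (−4.60) and Oat (−3.66) fell further than apolpp, and an effect of the diet on expression stays open and untested.

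Male HPLC replicate 4 held yolk protein reads, with Yp1 at 14339 against 17.5 to 63.2 in the other 9 male libraries. RNA in the proportions of the female libraries is argued against by the excess of Yp1 over that of Yp2, 1.68, where the 10 female libraries ran from 0.651 to 0.983. A female library under a male label is argued against by the share of 0.118%, since the lowest female share was 6.75%. RNA of another origin stays open, and no biological explanation was tested. Without this library 5365 male genes passed.

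In females 180 genes under 20 on HPLC rose at least 2-fold on LPHC and had neighbours on both sides in the BDGP6 reference annotation, whose build may differ from the authors'. Read-through from an upstream gene may contribute: 51.1% had a same-strand gene that overlapped them or lay within 5000 bases upstream. The share was 35.4% among 426 low-level genes that were not called (odds ratio 1.90, Fisher exact p = 0.000396). Downstream the shares were 33.3% and 30.8% (odds ratio 1.13, Fisher exact p = 0.566). Neighbours of the same name family were left out, except where either name was a CG number. With same-family neighbours kept, the upstream genes had a median LPHC value of 963 for genes that rose and 282 for genes not called. Read-through in proportion to the upstream gene is argued against. With same-family neighbours left out, the upstream genes of those that rose had a median log2 change of 0.18. The 92 genes below them, which were chosen for their rise, had one of 2.06 (median difference 1.72). Only a larger share of read-through on LPHC therefore stays open. Genomic DNA is argued against by a median rise of 0.754 over 1585 genes under 5 on HPLC. RNA of male reproductive tissue and induction by diet, which is untested, cannot be told apart, since the 12 list members in the table went both ways (median change −0.0488): Est-6, the most abundant, stood at 4091 on HPLC and 2820 on LPHC, Acp36DE at 1.11 and 1.24, Acp98AB at 1.62 and 35.1 and Dup99B at 0.259 and 40.6.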

How the results depend on the processing

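The list tests between sexes and the fit without male HPLC replicate 4 as a named check were chosen after the data were seen; the other alternatives were planned. The male, female and between-sex gene counts stayed within 1.5 times their values in all settings run. Male calls ranged from 5354 to 7471 and female calls from 2609 to 3919 over pseudocounts, filters, scalings, robust moderation, the replicate block, edgeR and DESeq2. Of the limma calls, edgeR shared 5597 male and 2995 female genes and DESeq2 5707 and 3091. Scaling to the same total raised the genes shared in direction from 950 to 1965. It moved the median gene by 0.25 in males and 0.16 in females, in the same direction, and so turned small falls into rises. In females a fixed total also passes the lower yolk protein share on LPHC (7.74% of reads against 13.4%) on to all other genes. With an estimated correlation 0 lists passed in males, 0 in females and 0 between sexes, with smallest adjusted p of 0.146, 0.495 and 0.0817.

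Leaving out each library in turn gave 5265 to 5828 male, 2590 to 3355 female and 4801 to 5292 between-sex genes, 818 to 952 genes shared in direction, 829 to 1276 opposite, and 13 to 16 male, 9 to 14 female and 16 to 18 between-sex lists. Without male HPLC replicate 4, 5365 male genes passed. Over all alternatives, named genes kept direction and call in 3330 of 3335 values. They were chosen for large changes or small p, so this stability is partly built in. Of the other values, 4 lost the call (female Men), 1 gained it (female tobi without female HPLC replicate 4, −0.39, adjusted p = 0.0241) and 0 reversed. Of 1801 list tests 1697 kept the call, 69 lost it, 35 gained it and 0 reversed; the male haemocyte list gained it at the same total (0.00739), among others. The correlation between sexes moved from 0.03 to 0.09 with a filter of 50; the cause was not tested.

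The replicate numbers did not pair the libraries: correlations of same-numbered libraries ran from −0.13 to 0.00 in males and −0.23 to 0.05 in females (males other pairs −0.20 to 0.19, females −0.33 to 0.33), and for 0 of them was the best match its own number. With the replicate block 5354 male, 2609 female and 4644 between-sex genes and 796 shared genes passed, and 14 male, 11 female and 16 between-sex lists; female Men was lost (adjusted p = 0.0667). In simulated data 40% of changes of log2 0.32 were recovered in males and 44% in females; depth was not varied there, and libraries of a group differed by more than sampling noise (chi-square per degree of freedom 7.55 to 50.4), so what depth limits was not tested.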

Other observations

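The list test between sexes was chosen after the data were seen; the other tests of this part, the counts of splits included, were planned. Lists that did not pass in at least 1 sex held members that moved. Of 19 circadian clock genes 3 were higher and 10 lower in males (median −0.20, turning to 0.05 at the same total; camera adjusted p = 0.337), with the photoreceptor protein gene cry at −1.02 and the repressor gene cwo at −0.63 (−0.38 at the same total); in females 3 were higher and 3 lower of 19 (median −0.00, turning to 0.16 at the same total; adjusted p = 0.968) and vri rose by 0.99. Of 14 biogenic amine genes 6 were higher and 5 lower in males (median 0.07, and 0.32 at the same total; adjusted p = 0.935) and 2 higher and 5 lower in females (median −0.12, turning to 0.04 at the same total; adjusted p = 0.452), where ple, tyrosine hydroxylase, rose by 0.92. In males Rh2 (−2.68) and Rh5 (−1.41) fell, and of 23 photoreceptor markers 7 were higher and 3 lower (median 0.00 as deposited, 0.25 at the same total and 0.17 at the same upper quartile; adjusted p = 0.738). Among male insulin and TOR genes, 7 higher and 8 lower of 24 (median −0.05, turning to 0.20 at the same total; adjusted p = 0.738), Lst (−1.75) and foxo (−0.88) fell. Arc1 rose by 1.02 in males, where 8 of 18 activity-regulated genes were higher and 3 lower (median 0.13, and 0.38 at the same total; adjusted p = 0.186).

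In females the sugar list had 7 higher and 17 lower of 42 (8 and 20 adjusted over the list alone; median −0.16, turning to 0.01 at the same total; adjusted p = 0.0639), with the sugar-responsive factor gene sug at 1.61 and the amylase gene Amy-p at −1.04. It passed at the same total (0.0432) and without female HPLC replicate 4 (0.0494) or 5 (0.0426) or female LPHC replicate 5 (0.0418), but not with an estimated correlation (adjusted p = 0.813 with an estimated correlation). The lipid synthesis list had 6 higher and 9 lower of 21 (median −0.18; adjusted p = 0.878), with FASN2 at 1.29 and Elovl7 at 1.04. Female neuropeptides had 4 higher and 10 lower of 33 (median −0.13, turning to 0.03 at the same total; adjusted p = 0.0639), with Nplp3 at −0.92 and Ilp5 at −0.66 (11 lower adjusted over the list alone). They passed with no filter (0.0351) and without female HPLC replicate 4 (0.0237) or 5 (0.0426) or female LPHC replicate 4 (0.0170), but not with an estimated correlation (adjusted p = 0.813 with an estimated correlation). The fat body list had 7 higher and 6 lower of 16 in females (median 0.03, camera adjusted p = 0.968). Its share of reads, which includes the yolk protein genes, fell from 14.9% ± 1.11 on HPLC to 9.08% ± 0.835 on LPHC (exact permutation test p = 0.00794, adjusted p = 0.0159). In females muscle markers were 3 higher and 9 lower of 22 (median −0.27; adjusted p = 0.0836), neuron markers 0 and 3 of 19 (−0.13, turning to 0.03 at the same total; 0.0836), glia 5 and 6 of 20 (0.02; 0.968), lipolysis 5 and 3 of 24 (0.07; 0.289), gut enzymes 3 and 3 of 8 (0.27; 0.92), and the male reproductive tract list 2 and 1 of 5 (0.31; 0.233). Adjusted over the list alone, muscle had 3 and 11 and neurons 0 and 1. Muscle passed at the same total (0.0446) and without female HPLC replicate 5 (0.0259) or female LPHC replicate 5 (0.0269), and neurons with no filter (0.0497) and without female HPLC replicate 3 (0.0170) or female LPHC replicate 2 (0.0273). Neither passed with an estimated correlation (adjusted p = 0.813 for each with an estimated correlation). The haemocyte list was 3 higher and 10 lower of 16 in males (median −0.70, and −0.45 at the same total; adjusted p = 0.0637), with srp at −2.21, and 3 and 3 of 16 in females (−0.12, turning to 0.04 at the same total; 0.669; 4 lower adjusted over the list alone). The male list passed at the same total (0.00739), the same upper quartile (0.0141), with no filter (0.0397), and without male HPLC replicate 2 (0.0493) or 4 (0.0462) or male LPHC replicate 2 (0.0421) or 4 (0.0161), but not with an estimated correlation (adjusted p = 0.686 with an estimated correlation). Amino acid transporters were 4 and 9 of 22 in males (−0.14, turning to 0.11 at the same total; 0.304) and 7 and 2 of 23 in females (0.01; 0.437). Cuticle and trachea markers were 4 and 4 of 20 in males (−0.11, turning to 0.14 at the same total; 0.741) and 5 and 3 of 20 in females (0.13; 0.452). Olfactory and taste markers were 3 and 6 of 17 in males (−0.27; 0.349) and 5 and 1 of 15 in females (0.02; 0.274). Yolk and eggshell genes were 1 and 0 of 9 in males (−0.19, turning to 0.05 at the same total; 0.955) and 2 and 3 of 9 in females (0.15; 0.948). In males ribosome biogenesis was 3 and 4 of 30 (0.02; 0.955), heat shock and stress 6 and 1 of 21 (−0.00, turning to 0.24 at the same total; 0.411), and OXPHOS subunits 11 and 23 of 66 (−0.04, turning to 0.21 at the same total; 0.554). At the same total, medians were also over 1.5 times from those given for male ribosome biogenesis (0.27) and olfactory and taste markers (−0.02), and for female lipid synthesis (−0.02), fat body (0.20), muscle (−0.11), glia (0.18), lipolysis (0.24), gut (0.43), male reproductive tract (0.47), amino acid transporters (0.17), cuticle (0.30), olfactory and taste markers (0.18) and yolk genes (0.31). At the same upper quartile the medians of male amino acid transporters (0.02), cuticle (0.05), heat shock (0.16), insulin and TOR (0.12) and OXPHOS genes (0.12) and of female clock genes (0.02) turned too. Means lay on the other side of 0 from the medians for male amines (−0.12), heat shock (0.29), photoreceptors (−0.14) and ribosome biogenesis (−0.04) and for female clock (0.04), fat body (−0.01), glia (−0.00), lipid synthesis (0.05) and yolk genes (−0.07). The direction of camera differed from the median for male heat shock and yolk genes and for female fat body, glia, gut and yolk genes.

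Whether other splits of the libraries give as much was tested with 100 splits drawn in each case, the real one included. For the 5784 male and 3133 female genes, 1 of 100 splits, the real one, gave as many, and the highest of the others gave 0 and 0. Chance can be excluded there for the spread between these libraries. It cannot for that between cultures, since nothing says that the libraries of a group came from separate ones. For the 5106 between-sex genes 1 of 100 also gave as many (highest other 1), but these splits mix the diets within each sex. They ask whether diet matters in either sex, so they say nothing of a difference between the sexes. For the 950 shared genes 1 of 100 also gave as many (highest other 0), but splits that call almost no gene in either sex cannot share any, so this says nothing of the sharing itself. For the lists 36 of 100 splits gave as many as the 14 male lists (highest other 20). As many as the 11 female lists came from 17 (14), and as many as the 16 between-sex lists from 13 (19). Chance is therefore not excluded for the lists, but these counts cannot tell it from diet. With 5 libraries per diet no other split is balanced, so a part of the diet difference may remain in each.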
